A study of Mus musculus with 8 samples.

How the data were processed

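Messenger RNA was measured by paired-end sequencing (2 reads of 150 bases) of poly(A) libraries from mononuclear cells of mouse blood, taken by cardiac puncture and separated on a density gradient. The authors deposited a table of raw gene counts for 56748 genes, in which every value is a whole-number count, with gene names, biotypes and coordinates. Per the submitters' processing notes, adapters were removed with cutadapt 4.0, reads were trimmed with Trimmomatic 0.39 and aligned with HISAT2 2.2.1 to the mouse genome GRCm39 (mm39). The extraction text names a library preparation kit, so how RNA was extracted, and whether red cells were lysed before it, is not given in the sources used here. The program that counted reads, the annotation release and the strand setting are not given in the sources used here. Coordinates printed with the genes are those of the count table.

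Samples were grouped by their titles, 5 saline and 3 fucoidan. The treatment text of the fucoidan samples speaks of saline, whereas their titles and characteristics say fucoidan, and the titles were followed. The labels give 1 batch date for all libraries, so no batch could be separated from the groups or tested within them. The groups, the comparison, the tests, the alternatives, the rule for naming genes and the 61 gene lists (20 of cell types, 41 of pathways) were fixed before the data were examined. Lists with fewer than 5 measured members were not tested, which left 58: liver markers had 0 measured members, and the endothelial and the epithelial markers 4 each.

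Genes were filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3), which kept 14723, library sizes were scaled with TMM factors, and differences were tested with edgeR's quasi-likelihood test in robust mode. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are fucoidan over saline, and CPM values are TMM-scaled. The SE of a gene's log2 fold change was derived from the test. It is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. The common biological coefficient of variation was 0.188. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists tested. A cell type score is the mean over a list's members of log2 CPM centred on each gene's mean. Scores and library measures were compared by exact two-sided permutation tests in scipy 1.17.1 over all 56 arrangements, of which the smallest p is 0.0357. These arrangements ignore the replicate numbers, so any pairing of libraries is not accounted for. Such a score measures expression and is not a share of cells.

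Named genes are the 10 largest rises and 10 largest falls among called protein-coding genes without a clone-style name, with a mean of at least 1 CPM and no overlap between the groups, of which 9 rises and 10 falls are described. Added to these were up to 4 called members of each described list with the smallest p, or 1 or 2 members where none was called. Always named are Foxp3, Il10, Tgfb1, Ctla4, Pdcd1, Cd274, Ifng, Tnf, Il6, Il1b and Arg1, fixed for their roles in immune suppression and inflammation.

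Libraries were checked for duplicates, and none was found. Correlations between log2 profiles were 0.967 to 0.986 among saline libraries, 0.979 to 0.985 among fucoidan libraries and 0.947 to 0.977 between groups. Whether the replicate numbers pair libraries across groups was checked on expression with the group means removed. Libraries that share a number correlated at 0.177, 0.233 and 0.144, and the other pairs across groups at -0.261 to 0.144. Each fucoidan library correlated highest with the saline library of its own number, so pairing is not excluded. A fit with the replicate number as a block was therefore given beside the main counts. Saline replicates 4 and 5 have no like-numbered fucoidan library, so in that fit they add nothing to the difference between groups. The procedure was tested on simulated data made from these libraries, with 200 changed genes. edgeR recovered 20.9% of 1.5-fold, 46.3% of 2-fold and 92.4% of 4-fold changes, and 4.51% of its calls were false. DESeq2 had 16.5% and limma-voom 2.94% false calls. Camera called the raised list and 0 of 40 unchanged lists. The simulated genes were drawn independently of each other. The list result therefore does not cover correlation between genes, which in the real lists was estimated at up to 0.943, for platelet genes.

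Total counts of 13061703 to 16334932 per library gave 13203 to 15076 genes with at least 10 counts. Alternatives were other scaling factors (median of ratios, upper quartile, dominant genes left out), DESeq2 1.42.0, limma-voom with quality weights, no filter or at least 10 counts in every library, a fold threshold, the replicate block, 1 surrogate variable (sva 3.50.0), camera with an estimated correlation, fry, other forms of the scores, and leaving out each library. Scaling on leukocyte genes, the erythroid or platelet score as a covariate, and lists without shared members were added after the data were seen. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.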

Results

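Peripheral blood mononuclear cells were profiled by poly(A) RNA sequencing in male C57BL/6J mice that received fucoidan or saline by daily gavage for 1 month. Fucoidan is a sulphated polysaccharide of brown seaweeds, here from Undaria pinnatifida, given at 200 mg per kg per day. There were 5 saline libraries and 3 fucoidan libraries, each titled as a biological replicate. Total counts per library ran from 13061703 to 16334932, with a mean of 15890000 ± 375000 (SD, n = 5) after saline and 14250000 ± 1404000 (SD, n = 3) after fucoidan (exact two-sided permutation p = 0.107, adjusted p = 0.129 over 6 library measures). Haemoglobin transcripts took 5.40 ± 1.88% of counts (SD, n = 5) after saline and 17.3 ± 5.93% (SD, n = 3) after fucoidan, a ratio of 3.20, with ranges of 3.51 to 8.48% and 13.5 to 24.1%. The exact two-sided permutation p for that share was 0.0357, the smallest that 56 arrangements allow, and 0.0536 after adjustment. Transcripts of ribosomal proteins took 6.17 ± 0.301% (SD, n = 5) and 4.09 ± 0.635% (SD, n = 3), and immunoglobulin transcripts 0.803 ± 0.0716% and 0.444 ± 0.126%, also without overlap between the groups. Such shares also fall where haemoglobin takes more of the total. The ratios of these mean shares were 0.662 and 0.554. With TMM scaling the median fold change was 0.854 for ribosomal protein genes and 0.720 for immunoglobulin V genes, a part of the immunoglobulin genes. Of the variance in log2 expression, 43.5% lay on a first component that placed the saline libraries between -33.56 and -14.0 and the fucoidan libraries at 29.27, 27.77 and 65.01, the last being fucoidan replicate 3.

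**Figure D1:**
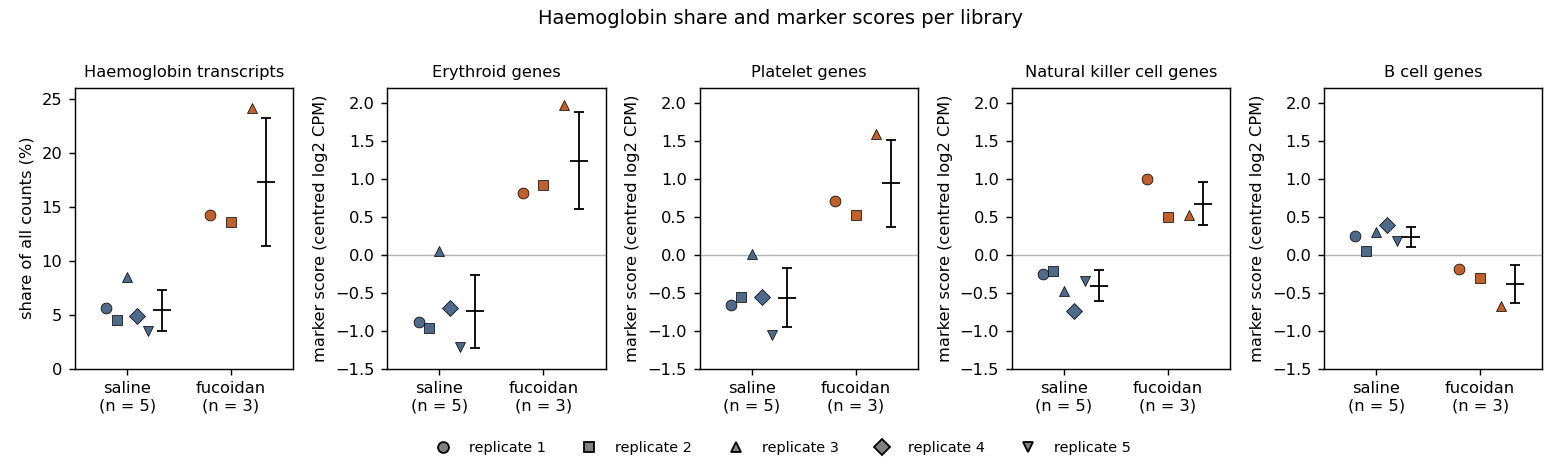
Haemoglobin share of all counts in percent, and 4 marker scores (mean centred log2 CPM over a fixed list), for each of 5 saline and 3 fucoidan libraries, with the group mean and SD beside the points. Every fucoidan library lies above every saline library for haemoglobin (13.5% or more against 8.48% or less), erythroid, platelet and natural killer genes, and below for B cell genes.

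The comparison of fucoidan with saline asks how a month of oral fucoidan changes the immune transcriptome of blood cells and their composition. Of the 14723 genes tested, 2025 changed, 1341 higher and 684 lower with fucoidan. The largest rise was that of Apol11a, a member of the apolipoprotein L family (ENSMUSG00000091650, GRCm39 chromosome 15, 77392471 to 77402251), at 9.17-fold (log2 3.20, SE 0.606, adjusted p = 0.00643). Its relative Apol11b (ENSMUSG00000091694, chromosome 15, 77518146 to 77527486) rose 8.11-fold, from 28.7 ± 9.92 CPM (SD, n = 5) to 233 ± 187 CPM (SD, n = 3). Hba-a2, an alpha chain of adult haemoglobin (ENSMUSG00000069917, chromosome 11, 32246489 to 32247298), rose 8.20-fold (log2 3.04, SE 0.367, adjusted p = 0.00396), though reads of its near-identical copy Hba-a1 cannot all be kept apart from its own. Genes of the red cell were among the other large rises: Dmtn, which encodes dematin of the membrane skeleton (log2 2.72, SE 0.513), and Tspo2, an erythroid translocator protein (log2 2.59, 12.7 to 76.6 CPM). Vangl1, the histone gene H2bc24, Cdr2 and Syngr1 rose by log2 2.65, 2.56, 2.45 and 2.40. With the erythroid score as a covariate Apol11b, Vangl1 and Cdr2 stood at 0.26, 0.18 and 0.093, and H2bc24 and Syngr1 at 2.78 and 1.36, all without a call. That fit called 0 genes in all, and its covariate correlates with the group at 0.899. Its values for single genes, here and below, therefore cannot part red cell content from treatment.

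The largest fall was that of C4b, a component of the classical complement pathway (ENSMUSG00000073418, chromosome 17, 34947354 to 34962856). It went from 4.77 ± 3.40 CPM (SD, n = 5) to 0.730 ± 0.134 CPM (SD, n = 3), a log2 change of -2.72 (SE 0.723, adjusted p = 0.0295). Prg4, which encodes the lubricant proteoglycan 4 (ENSMUSG00000006014, chromosome 1, 150325163 to 150341916), went from 10.6 to 1.78 CPM (log2 -2.55, SE 0.577). Mrc1, the macrophage mannose receptor (ENSMUSG00000026712, chromosome 2, 14234203 to 14336868), went from 7.44 ± 2.46 to 1.88 ± 0.403 CPM (log2 -1.96, SE 0.311, adjusted p = 0.00396). Of 7 macrophage markers 1 rose and 1 fell, 1 and 4 when adjusted over the list alone. Their median was -1.65, but the list did not stand apart by camera (adjusted p = 0.105) and its score overlapped (exact permutation p = 0.107). Among saline libraries this score, C4b and Prg4 were all highest in replicate 3 and lowest in replicate 4, while Mrc1 was lowest in replicate 3. Whether other cells or tissue account for this was not tested. Ptgs2, the inducible cyclooxygenase (ENSMUSG00000032487, chromosome 1, 149975782 to 149983978), went from 28.5 to 8.26 CPM (log2 -1.78, SE 0.425, adjusted p = 0.0182). Egf, Opn3, Zc3h6, Irgc1, Rwdd3 and Cgnl1 fell, with log2 changes of -2.10, -2.05, -1.86, -1.80, -1.71 and -1.56. With the replicate number as a block Ptgs2, Rwdd3 and Cgnl1 did not pass (adjusted p = 0.359, 0.0694 and 0.0752). C4b, Prg4, Irgc1, Ptgs2, Rwdd3 and Cgnl1 did not pass without fucoidan replicate 3 (adjusted p = 0.122, 0.105, 0.0553, 0.134, 0.123 and 0.0937). Limma-voom did not call C4b, Prg4 and Rwdd3 (0.159, 0.102 and 0.0837), nor did a fit with 1 surrogate variable call Rwdd3 (0.0526). Other libraries also decided some of them: C4b was not called without saline replicate 3 or 5 or fucoidan replicate 1 or 2 (0.0509 to 0.112), Prg4 without fucoidan replicate 1 (0.0694), Irgc1 and Ptgs2 without fucoidan replicate 2 (0.0502 and 0.0912), Rwdd3 without saline replicates 1, 2 or 4 or fucoidan replicates 1 or 2 (0.0605 to 0.156), and Cgnl1 on leaving out any saline library or fucoidan replicate 1 (0.0523 to 0.115).

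**Figure D2:**
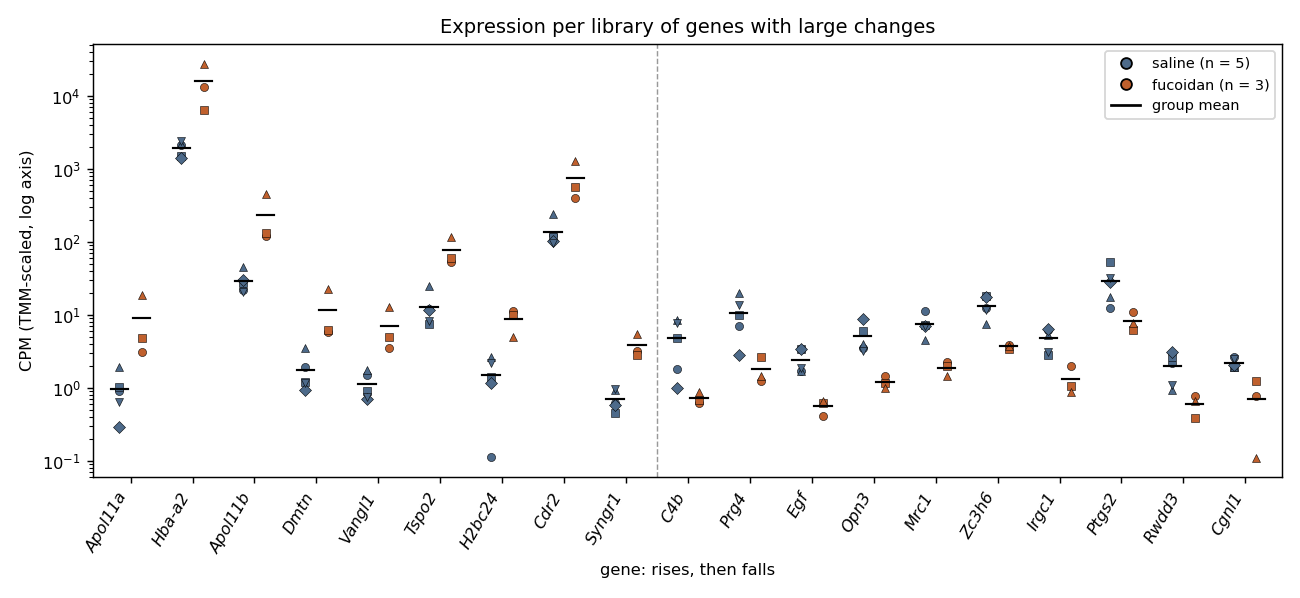
CPM on a log axis in each of 5 saline and 3 fucoidan libraries for 9 of the 10 genes with the largest rise and the 10 with the largest fall that passed the test without overlap between the groups; bars mark group means. Hba-a2 lay at a mean of 1912 CPM after saline and 15686 CPM after fucoidan, and C4b at 4.77 and 0.730 CPM.

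Those 2025 genes were called by edgeR's quasi-likelihood test at an adjusted p under 0.05; 797 of the rises and 125 of the falls were at least 2-fold. Of all tested genes, 3328 (22.6%) had no overlap between the groups, where chance gives 3.57%. Without fucoidan replicate 3, 928 genes passed (746 higher, 182 lower), and without saline replicate 4, 1291 (966 higher, 325 lower); the number of falls was also 447 without saline replicate 3, 365 without fucoidan replicate 1 and 315 without fucoidan replicate 2. With the replicate number as a block, 1561 genes passed (1122 higher, 439 lower), H2bc24 did not (adjusted p = 0.192), and the split was 1241 higher and 989 lower with upper-quartile factors, 1592 and 1122 with 1 surrogate variable, and 1648 and 1063 with limma-voom. With no filter on low counts Apol11a, Dmtn, H2bc24, C4b, Prg4, Ptgs2 and Tbx21 no longer passed, and without fucoidan replicate 3 Apol11a, Hba-a2, Apol11b, Dmtn, Vangl1 and Cdr2 stood at log2 2.05, 2.37, 2.14, 1.80, 1.94 and 1.83. Cgnl1 stood at -2.16 without fucoidan replicate 2, and Apol11a at 2.50 with the block.

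Genes of red cells and platelets rose as groups. Among 20 measured erythroid markers 19 rose and 0 fell, with a median log2 change of 2.22; Tfrc, the transferrin receptor, was the exception at -0.02. Fech, the last enzyme of haem synthesis, went from 428 ± 183 CPM (SD, n = 5) to 2068 ± 1111 CPM (SD, n = 3), and the exonuclease gene Isg20 from 203 to 1016 CPM, while Fam210b, a mitochondrial protein of erythroid maturation, rose by log2 1.73 (SE 0.248). All 19 measured platelet and megakaryocyte markers rose, by log2 1.34 to 1.63 with a median of 1.54. Among them were Alox12, the platelet lipoxygenase (379 to 1150 CPM), Treml1, a receptor of platelet granules (108 to 331 CPM), Gng11 (log2 1.54, SE 0.240) and Rgs18 (log2 1.46, SE 0.223). Adjusted over the list alone, 19 erythroid and 19 platelet genes rose. Both lists stood apart from the other genes by camera (adjusted p = 3.25e-14 each), and both had adjusted p = 0.523 with an estimated correlation. The erythroid score was higher by 1.98 and the platelet score by 1.51 in 3 of 3 fucoidan libraries against all saline libraries (exact p = 0.0357, adjusted p = 0.0759 for each).

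Natural killer and cytotoxic genes were higher with fucoidan. All 15 measured natural killer markers rose, by log2 0.84 to 1.40 with a median of 1.10. Prf1, which encodes the pore-forming protein of cytotoxic granules, went from 49.9 ± 4.96 CPM (SD, n = 5) to 112 ± 30.8 CPM (SD, n = 3), a 2.26-fold rise (log2 1.17, SE 0.153). Klrk1, the activating receptor NKG2D, and Klre1, a lectin-like receptor, rose by log2 1.15 and 1.27, and the serine protease Gzmb by log2 1.29 (SE 0.193). Of 14 cytotoxic granule genes 9 rose and 0 fell, with a median of 0.71, and these included Gzma (log2 1.10) and Serpinb9, an inhibitor of granzyme B (log2 1.02). Of 10 CD8 T cell markers 5 rose and 0 fell, with a median of 0.68: Ccl5 (log2 0.83), the receptor chain Klrd1 (0.68), the transcription factor Eomes (0.93) and the granule protein Nkg7 (0.83) had the smallest p, and natural killer cells express them too. Adjusted over the list alone, 15, 11 and 8 members of these 3 lists rose. By camera their adjusted p was 2.25e-11, 5.54e-08 and 3.66e-06, and each had adjusted p = 0.523 with an estimated correlation. Scores of natural killer and CD8 T cell genes were higher by 1.08 and 0.65 in 3 of 3 fucoidan libraries (exact p = 0.0357, adjusted p = 0.0759), the same libraries whose haemoglobin share was 13.5% or more. Without fucoidan replicate 1, 9 of the natural killer markers passed. Other lists hold 4, 8 and 5 of the members, and the CD8 list without its 5 had a median of 0.38.

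Some shared T cell genes and genes of T cell receptor signalling were higher. Of 18 shared T cell markers 3 rose and 0 fell, with a median log2 change of 0.34, and of 25 signalling genes 7 rose and 0 fell, with a median of 0.39. Lck, the kinase that starts signalling at the receptor, went from 170 ± 15.01 CPM (SD, n = 5) to 256 ± 37.4 CPM (SD, n = 3), while Prkcq and the adaptor Lat rose by log2 0.72 (SE 0.158) and 0.65 (SE 0.147). With the erythroid score as a covariate Lck, Prkcq and Lat stood at 0.47, 0.14 and 0.029 without a call. With the platelet score as a covariate they stood at 0.40, 0.11 and 0.035, also without a call. The signalling list had a median of 0.28 with the erythroid score and 0.26 with the platelet score, and kept its call with each. There were 14 rises among shared markers, and 15 rises and 1 fall among signalling genes, when adjusted over the list alone. Camera gave adjusted p = 1.01e-05 and 1.41e-04, with adjusted p = 0.523 with an estimated correlation for both. Among 10 markers of CD4 and regulatory T cells 4 rose and 0 fell, also when adjusted over the list alone, but the list did not stand apart (adjusted p = 0.0960). Its member Izumo1r, the folate receptor 4 of regulatory T cells, rose by log2 0.52 (SE 0.117), a call that ended with the replicate block (0.52) and without fucoidan replicate 1 (0.48) or 2 (0.52). Scores of shared T cell genes and of CD4 and regulatory T cell genes were higher by 0.38 and 0.27 in 3 of 3 fucoidan libraries, those with the high haemoglobin share (exact p = 0.0357, adjusted p = 0.0759), and the latter overlapped when taken as the median over members (exact p = 0.0714). Foxp3, the lineage factor of regulatory T cells, had a log2 change of -0.09 (SE 0.184, adjusted p = 0.800), and 0.0165 without fucoidan replicate 1. The number of shared T cell markers that rose was 6 without saline replicate 2 and 1 without saline replicate 3, fucoidan replicate 1 or fucoidan replicate 3, and that of signalling genes 4 without saline replicate 4 and 3 without fucoidan replicate 3. Without fucoidan replicate 3 the log2 changes of Prkcq and Lat were 0.48 and 0.41, and the CD4 and regulatory count was 1 or 2 when saline replicate 1, 3 or 4 or any fucoidan library was left out.

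B cell genes moved the other way. Of 15 measured B cell markers 12 fell and 0 rose, with a median log2 change of -0.65. Fcer2a, the low-affinity IgE receptor CD23, went from 376 ± 76.3 CPM (SD, n = 5) to 169 ± 25.5 CPM (SD, n = 3), a log2 change of -1.15 (SE 0.179), and Cd22, an inhibitory co-receptor, from 544 to 297 CPM. The adaptor Bank1 and Ralgps2 had log2 changes of -0.89 and -0.87. Genes of MHC class II presentation, by which B cells, monocytes and dendritic cells show antigen to helper T cells, fell in 11 of 12 cases with a median of -0.86. H2-Eb1 went from 1799 ± 269 to 952 ± 123 CPM, and H2-Eb2, H2-Oa and H2-DMa had log2 changes of -1.17, -1.19 and -0.86. Of 22 genes of B cell receptor signalling 9 fell and 0 rose, with a median of -0.33, among them Rasgrp3 (log2 -0.76) and the complement receptor Cr2 (log2 -0.61). Of 181 immunoglobulin V genes 16 fell and 0 rose, with a median of -0.47; Igkv6-15 was at -0.68, and reads of similar V genes cannot all be kept apart. Adjusted over the list alone, 12 B cell markers, 11 class II genes, 14 receptor signalling genes and 0 V genes fell, and 2 receptor signalling genes rose. Camera gave adjusted p = 2.43e-07, 1.19e-08, 0.00462 and 3.25e-14 in that order, and each list had adjusted p = 0.523 with an estimated correlation.

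The B cell score was lower by 0.62, at -0.386 ± 0.255 (SD, n = 3) after fucoidan and 0.232 ± 0.130 (SD, n = 5) after saline, in 3 of 3 fucoidan libraries (exact p = 0.0357, adjusted p = 0.0759), the libraries with the high haemoglobin share. Without the 9 members that other fixed lists hold, the receptor signalling list had a median of 0.04. Without fucoidan replicate 3, 6 B cell markers, 4 receptor signalling genes and 1 V gene fell, and 4 V genes with the replicate block. The receptor signalling count was 5 without saline replicate 3 or 4 or fucoidan replicate 2, and the V gene count was 29, 6, 5, 9, 9 and 7 without saline replicates 2, 3, 4 and 5 and fucoidan replicates 1 and 2. Of 13 plasma cell genes 3 fell and 0 rose, and that list did not stand apart (adjusted p = 0.102); 1 fell without saline replicate 4, and 0 without fucoidan replicate 1 or 3.

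**Figure D3:**
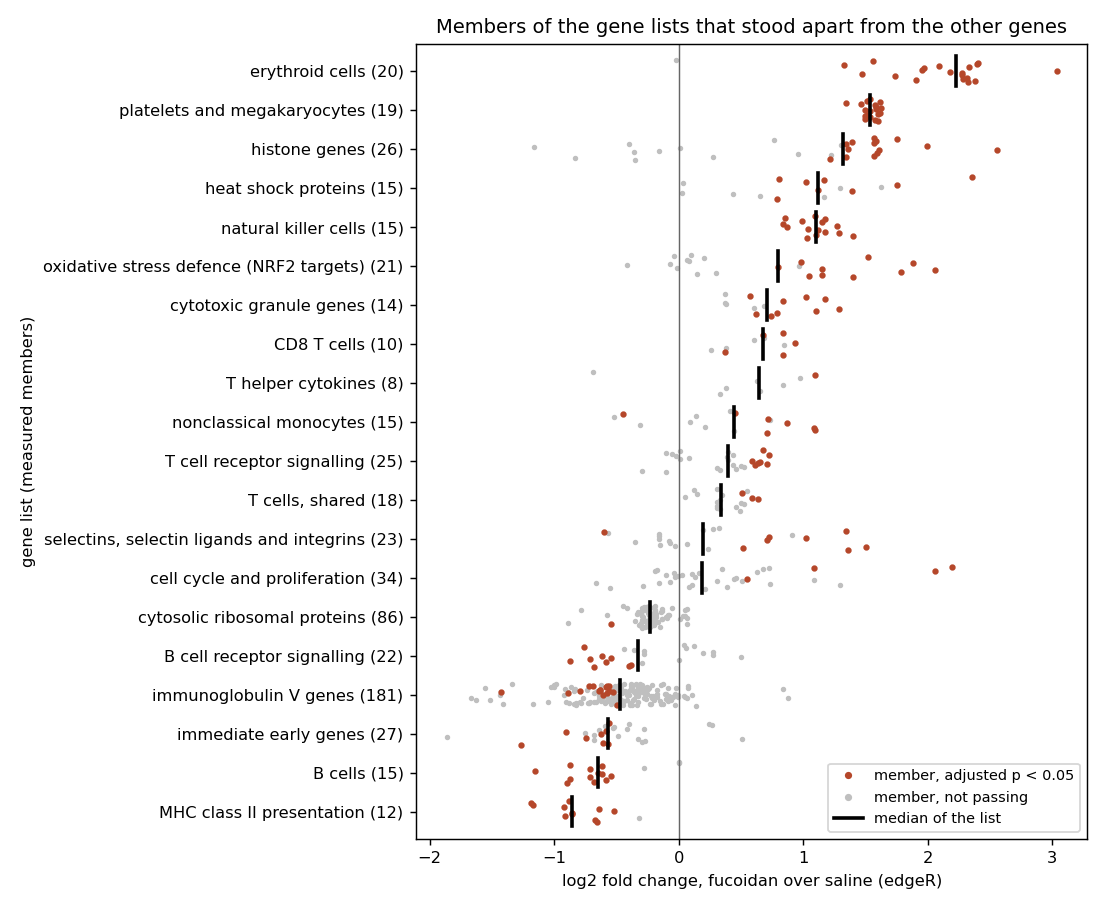
Log2 fold change, fucoidan over saline, of every measured member of the 20 fixed gene lists that stood apart from the other genes by camera, with the number of measured members in parentheses, red points for members at an adjusted p under 0.05, and bars at list medians. Medians run from 2.22 for erythroid genes to -0.86 for MHC class II genes, and the 181 immunoglobulin V genes have a median of -0.47.

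Some markers of nonclassical monocytes were higher. Of 15 markers of this patrolling subset 6 rose and 1 fell, with a median log2 change of 0.44. The scavenger receptor Cd36 went from 51.6 ± 4.38 CPM (SD, n = 5) to 110 ± 22.98 CPM (SD, n = 3), though platelets and red cell precursors express it too, and the integrin Itgax, the receptor Cd300e and the phosphatase Dusp16 rose by log2 0.72, 1.09 and 0.87. With p adjusted over the list alone, 8 rose and 1 fell. Camera gave adjusted p = 0.00262 and adjusted p = 0.523 with an estimated correlation, and the score was higher by 0.38 (exact p = 0.0357, adjusted p = 0.0759), a separation lost with the median over members (exact p = 0.0714). Of 19 classical monocyte markers 1 rose and 2 fell, the riser being Gpx1, which erythroid cells also express; the median was -0.28 (adjusted p = 0.450) and 0.06 without saline replicate 1, and the falls numbered 1 without saline replicate 4 or fucoidan replicate 2 or 3. None of 18 neutrophil markers passed edgeR's test; their median was -0.07, their mean 0.02 and the list's adjusted p 0.911. Genes of selectins, selectin ligands and integrins, through which leukocytes attach to vessel walls and to which sulphated polysaccharides can bind, rose in 7 of 23 cases and fell in 1, also when adjusted over the list alone, with a median of 0.20. Itgb1, Itgb2, Itgal and Cd24a rose by log2 1.03, 0.72, 0.71 and 1.36, in the libraries where red cell and platelet genes were high; with the erythroid score as a covariate they stood at 0.22, 0.65, 0.87 and -0.0781. That list had adjusted p = 0.0363 by camera, adjusted p = 0.523 with an estimated correlation, and no call with 1 surrogate variable (median 0.16), the replicate block (0.08) or without saline replicates 2, 3 or 4 (0.12, 0.12 and 0.16) or fucoidan replicate 3 (0.02).

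Genes of immune suppression and inflammation, which the study's title brings forward, gave few calls. Il1b, the inflammasome cytokine, went from 267 ± 62.5 CPM (SD, n = 5) to 142 ± 22.1 CPM (SD, n = 3), a log2 change of -0.92 (SE 0.198, adjusted p = 0.0114), and -0.79 without fucoidan replicate 2, when it no longer passed. Tgfb1, Cd274, Ifng, Tnf and Il6 had log2 changes of 0.26, -0.32, 0.38, -0.69 and -0.86, with adjusted p from 0.197 to 0.711. Leaving out 1 library moved these values over 0.15 to 0.34, -0.51 to -0.12, 0.17 to 1.06, -0.89 to -0.18 and -1.18 to -0.49, and none passed; without saline replicate 2, Ifng was at 1.06, Tnf at -0.18 and Cd274 at -0.12. Also without a call, Ifng was at 0.91 with 1 surrogate variable, 0.83 with limma-voom and 0.76 with the replicate block, Cd274 at -0.20 with 1 surrogate variable, Tnf at -0.45 with 1 surrogate variable and -0.36 with limma-voom, and Il6 at -0.23 with limma-voom. With the replicate block Il6 passed, at -1.32. The receptor genes Ctla4 and Pdcd1 had log2 changes of -0.56 (adjusted p = 0.183) and 1.10 (adjusted p = 0.182), and Ctla4 passed at -0.74 without saline replicate 1, while Pdcd1 was at 0.26 without fucoidan replicate 3 and 0.71 with limma-voom. Il10 and Arg1, with 0 to 9 and 2 to 9 counts per library, were too low to test. Of 22 checkpoint and inhibitory receptor genes 4 rose and 1 fell, also when adjusted over the list alone, without the list standing apart (adjusted p = 0.318); Havcr2, the receptor TIM-3, went from 10.9 ± 1.54 CPM (SD, n = 5) to 22.4 ± 2.66 CPM (SD, n = 3), and Cd244a, a natural killer receptor, rose by log2 0.56. Without fucoidan replicate 2 or 3 the number of rises in that list was 2. Of 21 immunosuppressive mediators 1 rose, the galectin Lgals1 (log2 0.50), and 2 fell, Mrc1 and Ptgs2 (adjusted p of the list 0.450, the same counts adjusted over the list alone), and Lgals1 did not pass with the replicate block (0.40) or when any 1 of saline replicates 2 to 5 or fucoidan replicates 1 and 3 was left out (0.37 to 0.51). The falls in that list numbered 1 without fucoidan replicate 2 or 3. Of 18 inflammatory cytokine and chemokine genes 1 rose and 2 fell (adjusted p = 0.911), the falls numbering 0 without fucoidan replicate 2 and 1 without fucoidan replicate 3.

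Of 8 T helper cytokine genes 1 rose and 0 fell, also when adjusted over the list alone: Tbx21, the transcription factor of type 1 helper and natural killer cells, at log2 1.10 (SE 0.304, adjusted p = 0.0347). The list's median was 0.64, with adjusted p = 0.0245 by camera and adjusted p = 0.523 with an estimated correlation, and its score overlapped between the groups (exact p = 0.107). Its call ended with the replicate block (0.72) and without saline replicate 3 (0.55) or fucoidan replicate 3 (0.48), and that of Tbx21 with no filter on low counts (1.09), with the block (1.10) and without saline replicates 1 or 4 or any fucoidan library (0.94 to 1.202).

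About as many chaperone, antioxidant and histone genes rose as did not pass. Hspa4l, a member of the HSP110 chaperone family (ENSMUSG00000025757), had the smallest p of all genes and went from 22.9 ± 1.55 CPM (SD, n = 5) to 77.2 ± 2.25 CPM (SD, n = 3), a 3.36-fold rise (log2 1.75, SE 0.0907, adjusted p = 9.14e-06). Of 15 heat shock genes 8 rose and 0 fell, with a median of 1.12, among them Hsp90ab1 (1268 to 2755 CPM). Of 21 oxidative stress defence genes 10 rose and 0 fell, with a median of 0.80: Prdx2, a peroxiredoxin, went from 216 to 798 CPM, Gpx1, a glutathione peroxidase, from 149 to 621 CPM, and Srxn1 and Cat, sulphiredoxin and catalase, rose by log2 1.52 and 1.40. Red cells carry much Prdx2, Cat and Gpx1, and the haemoglobin share was higher in the same 3 libraries. Without the 2 members that other lists hold, this list had a median of 0.30. Of 26 histone genes 14 rose and 0 fell, with a median of 1.32, including H2bc4 (85.8 to 262 CPM), H2bc15, H4c9 and H2bc6 (log2 1.59, 1.57 and 1.36). Most histone transcripts lack a poly(A) tail and several genes are near copies of each other, so their counts are uncertain. Adjusted over the list alone, 9, 12 and 17 members of these 3 lists rose. Camera gave adjusted p = 3.66e-06, 7.29e-06 and 2.88e-06, and each had adjusted p = 0.523 with an estimated correlation. The heat shock score was not separated (exact p = 0.0714): saline replicate 5, at 0.517, stood apart from the other saline libraries, at -1.03 to -0.0844, and above fucoidan replicate 3, at 0.162. The heat shock count was 3 without saline replicate 1, 5 without saline replicate 4, and 2, 3 and 5 without fucoidan replicates 1, 2 and 3. The histone count was 9 without fucoidan replicate 3.

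Nusap1 and Ube2c, which act in mitosis, rose from 20.8 ± 8.29 to 86.9 ± 39.2 CPM and from 30.9 ± 14.2 to 141 ± 59.9 CPM (SD, n = 5 and 3), in the libraries with the high haemoglobin share, and stood at log2 0.10 and 0.15 with the erythroid score as a covariate. Of 34 cell cycle genes 4 rose and 0 fell, with a median of 0.18. Isg15 and Rsad2, interferon-induced antiviral genes, rose by log2 2.12 (SE 0.288) and 2.32 (SE 0.371) in those same libraries, and stood at 0.26 and -0.14 with the erythroid score as a covariate, with Rsad2 at 1.70 without fucoidan replicate 3, while 5 of 34 type I interferon genes rose and 0 fell, also when adjusted over the list alone, and that list did not stand apart (adjusted p = 0.105). Of 27 immediate early genes 8 fell and 0 rose, with a median of -0.57; Fos went from 521 ± 20.3 CPM (SD, n = 5) to 310 ± 80.5 CPM (SD, n = 3), and Junb from 2249 to 1200 CPM. With the erythroid score as a covariate this list lost its call, at a median of -0.0535, and Fos and Junb stood at -0.30 and -0.40. Of 86 ribosomal protein genes 1 fell, Rpl22l1 (log2 -0.54, SE 0.146), and 0 rose, with a median of -0.23. Adjusted over the list alone, 5 cell cycle genes rose, 11 immediate early genes fell and 0 ribosomal genes changed. Camera gave adjusted p = 0.0218, 1.15e-04 and 1.16e-08 for the cell cycle, immediate early and ribosomal lists, each with adjusted p = 0.523 with an estimated correlation. Scores of the cell cycle and immediate early lists overlapped between the groups (exact p = 0.0714 each). The cell cycle list lost its call without saline replicate 3 (0.19) or fucoidan replicate 3 (0.19), its median was 0.34 without saline replicate 2 and 0.12 without saline replicate 4, and its count was 7 without saline replicate 2 and 2 with the replicate block. The immediate early count was 5 without saline replicate 3 or 5, 3 without saline replicate 4, and 1 and 2 without fucoidan replicates 2 and 3, when Junb did not pass (-0.86 and -0.76). Type I interferon rises numbered 3 without fucoidan replicate 3 and with the block, and Rpl22l1 did not pass without saline replicates 3 or 4 or fucoidan replicates 2 or 3 (-0.57 to -0.39).

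Of the 58 lists tested, 20 stood apart from the other genes by camera with a preset correlation of 0.01, 14 higher and 6 lower. With the correlation estimated for each list, camera called 0 of them; 3 had an unadjusted p under 0.05, the smallest being 0.0192. The self-contained test fry, which asks whether a list's genes move on balance one way, called 14 lists, and shared T cell, T cell receptor signalling, immediate early, cell cycle, T helper and selectin and integrin genes were not among them. All 20 lists and their directions stood with size factors by median of ratios or upper quartile, with dominant genes left out of the scaling, and with scaling on leukocyte genes. Of the 17 cell type scores, 8 placed every fucoidan library beyond every saline library, and 0 had an adjusted p under 0.05 by the exact permutation test.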

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

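Of the tests in this part, those of a single library, of granulocyte carry-over, of red cells and platelets left in the preparation, of dilution, of a lower share of B cells alone and of dividing cells, and those that scale on leukocyte reference genes or take the erythroid score as a covariate, were chosen after the result was seen. So was the fit with the platelet score as a covariate.

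Among 119 values examined in the saline group for a library far from the other 4, 3 had a gap above 0.71 of the group's range, where chance gives about 1 in 20, or 5.95. The neutrophil score of saline replicate 1 was 0.681 against -0.113 for the next library, a gap of 0.744 of the range. Ctla4 was lowest in saline replicate 1, at 3.23 against 4.38 on the log2 CPM scale, a gap of 0.842 of the range. Cd22 was highest in saline replicate 4, at 9.34 against 9.06 on that scale, a gap of 0.771 of the range. The fucoidan group of 3 was too small for this measure.

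Among the 56 splits of the 8 libraries into 5 and 3, the real one called 2025 genes and only 1 split, the real one, called as many. The highest of the others called 2. A share of 1 in 56 is under 0.05, which argues against chance as the source of the count but does not exclude it. Splits that mix the groups also carry the gap between them as spread, which lowers their counts. Nor can the splits tell the treatment from another difference that sets the same 3 libraries apart, such as their haemoglobin share. Of the 8 splits that part all 3 pairs of like-numbered libraries, each one other than the real split called 0 genes by edgeR, against at most 2 among the rest. If the numbers do pair the libraries, the real split is 1 of only 8, too few to reach a share under 0.05.

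Erythroid and platelet genes rose together in every fucoidan library. The rise is not that of 1 library, since without fucoidan replicate 3 the erythroid median was 1.73 with 17 members passing and the platelet median 1.199 with 19 passing. Distortion of the scaling by haemoglobin is argued against by a platelet median of 1.53 with the dominant genes left out, and carry-over of the cell pellet with its granulocytes by a neutrophil median of -0.0653 (SD of members 0.486), 2.29 below the erythroid median; without saline replicate 1, which stood apart, the neutrophil score was higher by 0.32 in all fucoidan libraries (exact p = 0.0571, the smallest possible) and the erythroid score by 1.94, so only carry-over in equal proportion is argued against. More red cells and platelets left in the preparation and an effect of fucoidan on these cells in the blood cannot be told apart, because the erythroid median of 2.22 is what both would give and each library was prepared from 1 treatment group. Whether red cells were lysed, and how RNA was extracted, is not given in the sources used here.

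Natural killer genes rose while B cell genes fell. Dilution of leukocyte RNA by red cell and platelet RNA would move both alike, but the natural killer score minus the B cell score was higher by 1.70 with fucoidan (SD 0.227 and 0.328), which restates the opposite directions already seen and adds no further test. A lower share of B cells alone would raise natural killer and T cell genes alike, but the natural killer minus T cell score was higher by 0.70 (exact p = 0.0357). Its SD was 0.423 with fucoidan and 0.0876 with saline, and it ran from 0.0661 to 0.897 in the fucoidan libraries. This score too restates differences already seen and adds no independent test. Scaled on leukocyte reference genes, the natural killer median was 1.06 and the B cell median -0.70, which argues against scaling on the whole library as the source of either sign. Scaling moves all genes of a library alike, so it cannot test the gap between the 2 lists. A shift in leukocyte composition with fucoidan may underlie both, as a hypothesis found and tested on the same data, and differences between the groups in cell separation or blood sampling remain open.

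Of 26 histone genes 14 rose and 12 did not pass, with a median of 1.32 and adjusted p = 0.523 for the list with an estimated correlation. More dividing cells were taken to bring S phase genes up by at least 0.66, a threshold set from the histone median after the result was seen. The median of 16 such genes was 0.13 and their mean 0.26, with 2 rising. The SE of 0.126 treats these genes as independent. Only a rise of that size is argued against, and a smaller one remains open. Histone transcripts brought by red cells or by platelets cannot be told apart from a rise within leukocytes. With the platelet score as a covariate the histone median was 0.12. With the erythroid score as a covariate it was 0.10, with a median SE of 0.733 against 0.347 before, and 0 members passed. In the same fit the natural killer median was 1.52 and that of heat shock genes 1.65, so not every difference shrank, but the score correlates with the group at 0.899 and edgeR called 0 genes. A biological cause within leukocytes was not tested.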

How the results depend on the processing

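Tests with the erythroid or platelet score as a covariate, with scaling on leukocyte genes, and of lists without shared members were chosen after the result was seen. Of the 2025 genes, the total stayed within 1.5 times under every other scaling, filter and tool (1902 to 2714), and the genes shared with each setting kept their direction. Of 87 named genes with a call, 69 kept it in all 18 settings other than the covariates, and Egf, Opn3 and Syngr1 kept it in those that tested them, not having 10 counts in every library. DESeq2 called 2533, limma-voom 2711 and 1 surrogate variable 2714 genes. The number of falls moved from 684 to 1122 with 1 surrogate variable and 1063 with limma-voom, and the cause was not tested. By construction, a log2 change of at least 1 beside the adjusted p left 922 genes (797 higher, 125 lower), and beside an unadjusted p 1215, of which 292 were lower. Leaving out 1 library gave 928 to 2224 genes, 746 to 1368 higher and 182 to 856 lower, with fewer samples in each fit. With the replicate number as a block, 439 genes were lower, and the lists of T helper cytokines and of selectins and integrins lost their calls, as did H2bc24, Ptgs2, Rwdd3, Cgnl1, Izumo1r, Tbx21 and Lgals1; the cause was not tested.

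Camera with an estimated correlation called 0 lists, 0 higher and 0 lower, as its construction widens the error of correlated genes. Fry had 9 lists higher, and camera with no filter 10 lower; the cause was not tested. The selectin and integrin list also lost its call with 1 surrogate variable (adjusted p = 0.0702). With at least 10 counts in every library the cell cycle, T helper and selectin and integrin lists lost their calls. The B cell receptor signalling list had a median of 0.0449 without the members that other lists hold.

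With the erythroid score as a covariate edgeR called 0 genes, 0 higher and 0 lower (828 at an unadjusted p under 0.05), and with the platelet score 3, of which 3 were higher and 0 lower (916). These scores correlate with the group at 0.899 and 0.880 and with each other at 0.991, and the median SE over all genes was 0.176 without and 0.38 and 0.351 with them. With each covariate 13 of the 20 called lists kept their call and 7 lost it: those of platelets, erythroid cells, oxidative stress defence, histones, immediate early genes, B cell receptor signalling, and selectins and integrins. The platelet and erythroid lists lost it by construction, since the covariates are the scores of these lists. With the erythroid score the median was -0.0535 for immediate early, -0.25 for B cell receptor signalling, 0.10 for histone and 0.10 for selectin and integrin genes. In the same fit the medians were 1.52 for natural killer, 1.14 for cytotoxic granule, 0.98 for nonclassical monocyte, 1.65 for heat shock, -0.98 for MHC class II and -0.53 for B cell genes. Klre1, Klrk1, Hspa4l and H2-Eb2 stood at 2.12, 1.97, 1.65 and -1.23 without a call, and with the platelet score Klrk1, Hspa4l and Cd300e passed. Other list medians with the erythroid score were 0.0912 for classical monocytes, 0.29 for neutrophils, -0.0337 for platelets, -0.00977 for erythroid cells and -0.0281 for oxidative stress defence. The genes Apol11a, Dmtn, Tgfb1, Tnf, Srxn1, Gpx1, Cat, Cd24a and Rsad2 were then at -0.39, -0.43, -0.17, 1.02, -0.0281, -0.0455, -0.13, -0.0781 and -0.14. With the platelet score the neutrophil median was 0.0349, and Dmtn, Tgfb1, Pdcd1 and Tnf were at -0.0858, -0.17, -0.17 and 0.0877.

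The neutrophil score taken as the median over members was -0.0564, against 0.13 as their mean, and in that form 7 of 17 scores separated the groups, those of nonclassical monocytes and of CD4 and regulatory T cells no longer (exact p = 0.0714 each). Without saline replicate 1 the neutrophil score did separate them, at 0.32. Leaving out 1 library moved the classical monocyte median between -0.36 and 0.0567, its score between -0.16 and 0.0457, and Foxp3 between -0.18 and 0.0165; none of these had a call, and the cause was not tested. Leave-one-out score tests have too few arrangements to reach a p under 0.05. Depth limits Il10 and Arg1, at 9 counts or fewer in each library.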

Other observations

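No test in this part was chosen after the result was seen; the genes below follow the rule for named genes, and no explanation is offered.

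Receptors that guide leukocytes through tissues went in both directions. Ccr6, a receptor of B cells and of type 17 helper T cells, went from 9.19 ± 1.63 CPM (SD, n = 5) to 4.42 ± 0.278 CPM (SD, n = 3), a log2 change of -1.05 (SE 0.186, adjusted p = 0.00510 by edgeR). Ccr7, which leads lymphocytes and dendritic cells to lymph nodes, went from 490 ± 95.8 to 270 ± 40.0 CPM (log2 -0.86, SE 0.169). S1pr5, the sphingosine phosphate receptor by which natural killer cells leave the bone marrow and lymph nodes, rose from 31.5 ± 6.41 to 58.8 ± 9.68 CPM (log2 0.90, SE 0.170). Of 21 measured chemokine receptor genes 2 rose and 4 fell, and adjusted over the list alone 5 rose and 5 fell; the list did not stand apart by camera (adjusted p = 0.939). The rises numbered 1 without saline replicate 3 or 4 or any fucoidan library, and the falls 2 without saline replicates 3, 4 or 5 or fucoidan replicates 2 or 3.

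Targets of glucocorticoids, the steroid hormones of the stress response, gave calls for single genes. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 27.6 ± 2.82 CPM (SD, n = 5) to 71.8 ± 14.1 CPM (SD, n = 3), a 2.60-fold rise (log2 1.38, SE 0.134, adjusted p = 0.00250 by edgeR). Il7r, the interleukin 7 receptor of T cells, rose by log2 0.77 (SE 0.133). Of 19 measured targets 3 rose and 0 fell, also when adjusted over the list alone, and the list did not stand apart by camera (adjusted p = 0.530). Among 23 complement and coagulation genes 4 rose and 3 fell, 6 and 6 when adjusted over the list alone (adjusted p = 0.968 for the list). Cd55, which protects cells from complement, went from 456 ± 59.7 to 216 ± 34.2 CPM (log2 -1.08, SE 0.147, adjusted p = 0.00396). The falls in that list numbered 1 without saline replicate 3 or any fucoidan library, and 6 with the replicate block.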
